A study of Mus musculus with 9 samples.

How the data were processed

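Messenger RNA of muscle from C57BL/6J mice, a common inbred laboratory strain, was measured by sequencing in 9 libraries, 3 in each of 3 groups. Per the labels, the mice were 9 weeks old at assignment, acclimatised for 2 weeks and then fed for 8 weeks. The control group received a diet with 10% of its energy from fat, and the other groups a high-fat diet with 60%. One of the high-fat groups also drank L-carnitine at 100 mg/kg/day. All mice were fasted for 6 h before collection. The labels do not name the muscle. They do not say that each library came from a separate mouse, so p-values measure the spread between these libraries.

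The libraries were made with a stranded mRNA kit, per the labels' protocols. Trim Galore 0.6.4, Bowtie2 2.4.2, HISAT2 2.2.0, HTSeq 0.13.5 and edgeR are named in the submitters' processing notes, without their roles. The same notes name the builds GRCh38, GRCm39 and Rnor_6.0. The strand setting used for counting is not given in the sources used here. The authors deposited whole-number counts per gene, not normalised, for 19335 features, with coordinates that are those of GRCm39. They also deposited FPKM values, and the ratio of a gene's FPKM to its count was checked to differ between libraries only as the count totals do (largest relative deviation 1e-14 over 2896 genes). Only the counts were tested. Alternatives that had been listed for a file with normalised values only did not apply.

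Counts per library totalled 2315985 to 3773649. Intervals for shares of a library's counts are Wilson 95% intervals, and a count of 0 allows up to 3 counts, which is 0.795 to 1.30 CPM (counts scaled to a common library total) here. Both cover counting error only, since reads amplified by PCR are not independent molecules.

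The reference annotation at hand (GENCODE M21) uses another build than the file: the start of only 377 of the 19097 features found in both is the same. It was therefore used only to tell which genes overlap which, and every coordinate given is the file's own. By M21, 6981 features share exon sequence with a gene on the opposite strand. Another 2870 overlap an opposite gene without shared exon sequence in M21, 9246 have no opposite gene, and 238 were not found. An overlap of gene spans in the file itself also counted as an opposite gene. For such overlaps exon sharing was not checked. These 3 classes of features are called opposite-exon features, features with an opposite gene but no shared exon in M21, and features with no opposite gene. Genes that share exon sequence with an opposite-strand gene are reported under the symbol in the file, with that opposite gene beside them.

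After the data had been seen, an opposite-exon feature was taken to stand for its partner where its total was at least 5 times the partner's own (1130 features). Counts on genes with no opposite gene were taken to stand for the genes themselves. This assignment is called the measured genes, and each class was scaled by its own normalisation factors. The rule gave some abundant genes, among them Gapdh, Des and Pfkm, to weakly counted neighbours. In 32 pairs the feature was on a fixed gene list and its partner was not, against 88 pairs with the reverse and 3 with both on a list. A strict version, added after this was seen, assigned only the 629 non-coding features. A residual rate was computed per library as the median of the partner's own count relative to that of the feature opposite it. It was taken over 497 pairs that met the 5-fold rule, with at least 500 counts on the feature and 90 on the partner. The rule itself keeps this rate low, so its level is not an unselected measurement.

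Genes were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test (robust) on the counts, with TMM normalisation and the default expression filter, which kept 7523 features. All 9 libraries entered one fit with 3 groups and no covariate. P-values were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, and an adjusted p below 0.05 was taken as changed. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of F. Group values are means of TMM-normalised CPM ± SD.

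Before the data were examined, 37 pathway lists and 15 cell type lists were fixed, 52 lists with 1125 entries. The 37 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over these lists. Estimated correlations and fry were run beside it. Fry tests whether a list's genes move, on balance, one way.

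Genes to be named were fixed by a rule before the data were examined. In each comparison it took up to 6 changed genes with the largest rise and 6 with the largest fall. These needed a mean CPM of at least 1 and no overlap between the groups' libraries, and predicted genes (Gm symbols, Rik symbols and pseudogenes) were skipped. Where no gene passed in a direction, the 5 with the smallest p were taken. The rule also took up to 4 members of each list that passed, those with the smallest p in the list's direction, a panel of 18 genes of lipid handling, atrophy and fibre type, and, for the reversal, genes changed by the diet. Every predicted feature named, and every other gene outside the rule, was chosen after its values were seen. A list member that the rule took is not reported here.

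The comparison of both fold changes for a reversal by carnitine shares the high-fat diet libraries. It was therefore set against 50 simulations of 9 libraries with no effect in any group.

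Alternatives listed before the data were examined were RLE normalisation, library totals without TMM, leaving out the 20 most abundant features, no filter, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the 6 libraries compared, the replicate number as a block, a 2-fold threshold and leaving out each library in turn. Alternatives added after seeing the data were each class of features alone, the measured genes by both rules, and the residual rate as a covariate.

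The tests were tried on simulated counts for the 7523 features, 200 of them changed, with the means, spread and library sizes of the real data. Of 100 genes changed 2-fold, 12% were recovered in the comparison of high-fat diet with control, 17% in carnitine against high-fat diet and 9% in carnitine against control. Of 100 changed 4-fold, 46%, 64% and 49% were recovered in the same order. False calls numbered 2 of 60, 8 of 89 and 2 of 60.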

Results

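Muscle RNA of mice was sequenced in 3 groups of 3 libraries: a control diet with 10% of energy from fat, a high-fat diet with 60%, and the high-fat diet with L-carnitine at 100 mg/kg/day in the drinking water for 8 weeks. L-carnitine carries long-chain fatty acids into mitochondria as acylcarnitines. The design asks what the diet changed in muscle, what carnitine changed on that diet, and whether carnitine moved expression back toward control. Counted reads totalled 2795397, 2315985 and 2992084 in control 1, 2 and 3, 2698129, 3773649 and 2553555 in high-fat diet 1, 2 and 3, and 2538389, 2598636 and 2319454 in carnitine 1, 2 and 3. Of 19335 features, 7523 were tested.

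Features annotated on the strand opposite to fast-twitch muscle genes held the largest shares of the counts. The feature with the most counts was Rabep2 (chromosome 7, 126027931 to 126048417, GRCm39), with 16.6% of all counts. It shares 763 bp of exon with Atp2a1, the calcium pump of fast fibres, whose own row held 3.33% as many counts. A930016O22Rik, opposite the muscle creatine kinase gene Ckm (451 bp shared), held 13.1% of all counts and Ckm itself 4.00% as many as that. Ube2c, a cell cycle gene opposite the fast troponin gene Tnnc2 (592 bp shared), held 9.48%. Together these 3 features took 39.2% of all counts. Features that share exon sequence with an opposite-strand gene held 84.6% of all counts, and features with no opposite gene 12.1%. A fold change of a feature with an opposite gene is therefore not a measurement of the named gene alone. The opposite gene is given beside features that share exon sequence with it. Features that overlap an opposite gene but share no exon with it in M21, such as Oacyl, are named without it. Were reads counted against the library's strand, as weighed below, a gene with no opposite gene would keep only a residue of its reads. That possibility limits the fold changes of such genes, and of lists that hold them, throughout.

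**Figure D1:**
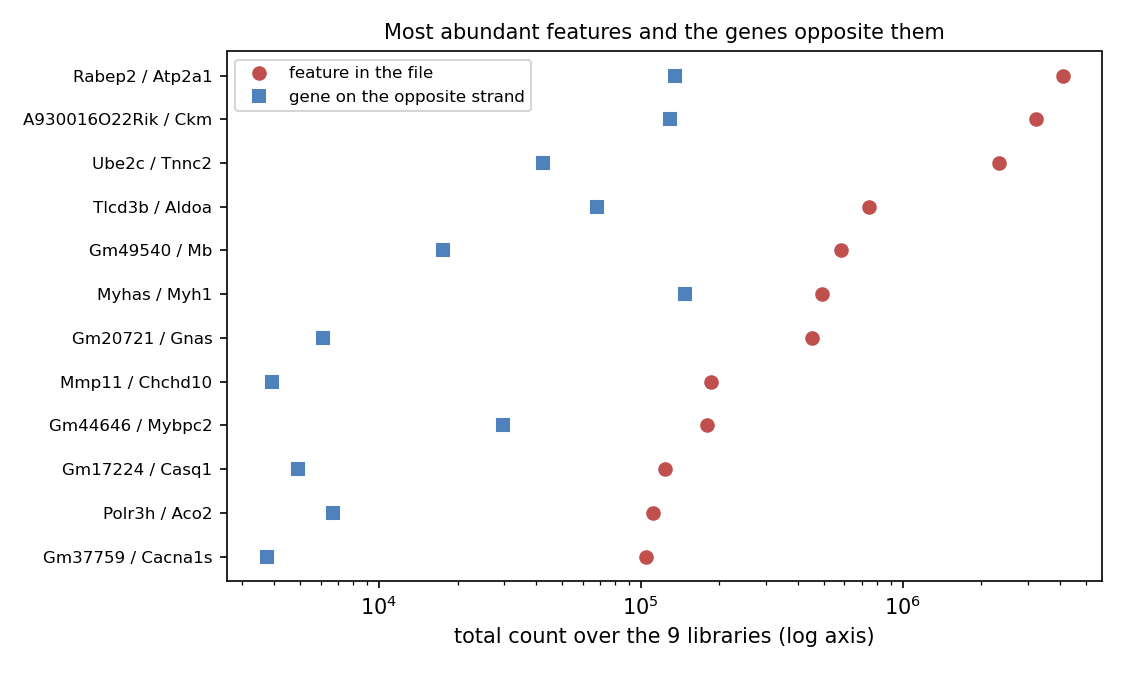
Total counts over the 9 libraries (log axis) of 12 abundant features, as red circles, and of the gene on the opposite strand of each, as blue squares. Only pairs in which the feature lies above the gene opposite it are shown, from Rabep2 with 4083208 counts against 135778 for Atp2a1 downward.

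Libraries also differed in how many counts fell on features with no opposite gene. These held 14.5% of the counts of control 1 (95% Wilson interval 14.4 to 14.5), 9.55% in control 2 (9.51 to 9.59) and 13.0% in control 3. In the high-fat diet libraries the shares were 11.8%, 13.1% and 14.2%. Carnitine 1 had 13.1%, whereas carnitine 2 had 8.65% (8.62 to 8.69) and carnitine 3 had 9.32% (9.28 to 9.36). The residual rate is the median count of a gene relative to the feature opposite it. Only pairs whose feature held at least 5 times the gene's total entered, which keeps its level low by selection. The rate averaged 8.07% ± 1.00 in control (SD, n = 3), 8.41% ± 1.15 on the high-fat diet and 6.74% ± 2.72 with carnitine. It was 9.88% in carnitine 1, against 5.32% in carnitine 2 and 5.03% in carnitine 3.

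**Figure D2:**
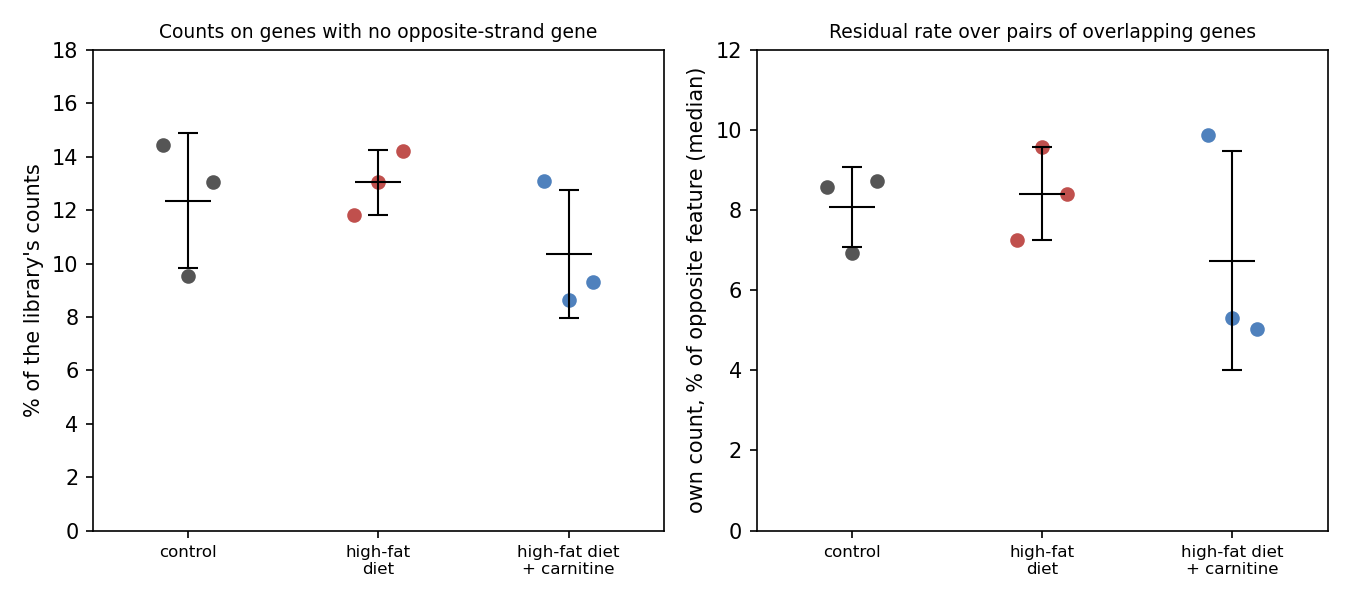
Left, the percent of each library's counts on genes with no opposite-strand gene; right, the residual rate per library in percent. Points are libraries, the long bars group means and the whiskers 1 SD (n = 3 per group); carnitine 2 and 3 (5.32% and 5.03%) have the lowest residual rates and carnitine 1 (9.88%) the highest.

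On the high-fat diet, 4 features fell against control and none rose. Slc25a25, a mitochondrial ATP-Mg/phosphate carrier (chromosome 2, 32304499 to 32341457; 379 bp of exon shared with Naif1), fell from 27.0 ± 12.4 to 2.38 ± 2.27 CPM (SD, n = 3 each). Its log2 fold change was −3.55 (SE 0.64, adjusted p = 0.0258 by edgeR's quasi-likelihood test). Zfp142, a zinc finger gene opposite the phospholipase C gene Plcd4 (2101 bp shared), fell from 153 ± 15.1 to 49.3 ± 8.42 CPM, a log2 fold change of −1.64 (SE 0.30, adjusted p = 0.0258). Tecpr2, an autophagy gene with no opposite gene, fell from 296 ± 64.6 to 113 ± 11.3 CPM (log2 fold change −1.39, SE 0.26, adjusted p = 0.0258). The non-coding feature Gm26714, opposite the transcriptional regulator gene Tcim, fell by 1.48 on the log2 scale (SE 0.29, adjusted p = 0.0392). The rises with the smallest p did not pass. Among them, the transcriptional co-regulator Cited2 was at 36.2 ± 2.41 against 11.4 ± 4.00 CPM (log2 fold change 1.65, adjusted p = 0.0776), Tacc2 at 1.09 (adjusted p = 0.0776), the splicing factor Rbm20 at 1.87 (adjusted p = 0.0836), the COPII coat gene Sec24a at 1.42 (adjusted p = 0.134) and the reticulophagy receptor Retreg1 at 1.16 (adjusted p = 0.156). At an unadjusted p below 0.05 there were 475 features. DESeq2 called 11 rises and 35 falls, and limma-voom 3 and 15. Each of the 4 features passed in 1 of the 6 fits that left out a library (adjusted p up to 0.409, without control 2), and the count was 13 without control 1, 0 without control 2 or high-fat diet 3, 1 without control 3 or high-fat diet 1, and 2 without high-fat diet 2. It was 0 without TMM, 68 without a filter, 40 with a filter on CPM or in a fit of the 6 libraries alone, and 10 with the replicate number as a block.

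Of the 37 lists tested, 2 passed as higher on the high-fat diet and 1 as lower. PPAR target genes, which include genes of fatty acid use, had 18 of 21 members higher (median log2 fold change 0.62, adjusted p = 0.000713 by camera). None of these members passed alone, over all genes or adjusted over the list alone. The thioesterase Acot2 was at 23.6 ± 8.82 against 4.71 ± 4.11 CPM (log2 fold change 2.26, SE 0.66, adjusted p = 0.260), and Pdk4, the kinase that inhibits pyruvate dehydrogenase, at 528 ± 22.01 against 344 ± 96.3 CPM (0.62, SE 0.27, adjusted p = 0.691). Mlycd was at 0.73 (SE 0.33), and Fabp3, opposite Gm10570 and Zcchc17, at 0.73 (SE 0.34). Mitochondrial fatty acid oxidation had 20 of 24 members higher (median 0.34, adjusted p = 0.0426), with 0 passing over all genes or adjusted over the list alone. Among them Acadl was at 1.17 (SE 0.37), Decr1 at 1.44 (SE 0.66) and Hadhb at 0.94 (SE 0.54). Immediate early genes, the first transcripts induced by many stimuli, had 9 of 13 members lower (median −0.49, adjusted p = 0.0453). Of these, 2 fell when adjusted over the list alone, Klf2 (log2 fold change −3.79, SE 0.91) and Nr4a1 (−1.92, SE 0.50), and 0 over all genes (adjusted p = 0.0985 and 0.135). Jun, opposite Junos, was at −0.75 (SE 0.33) and Jund, opposite Gm11175, at −0.66 (SE 0.31). With an estimated correlation none of the 37 lists passed (smallest adjusted p = 0.901 with an estimated correlation), and fry called 0. With the measured genes, each class scaled by itself, 3 lists passed as higher and 5 as lower. Fast fibre proteins (15 of 16 lower, adjusted p = 2.08e-07), calcium handling (12 of 14 lower, adjusted p = 0.00540), cytosolic ribosomal proteins (46 of 59 lower, adjusted p = 0.00163) and glycolysis (9 of 12 lower, adjusted p = 0.0302) then joined immediate early genes, and insulin signalling (8 of 11 higher, adjusted p = 0.0413) joined the lists that passed as higher. None of these passed with an estimated correlation (smallest adjusted p = 0.183 with an estimated correlation). By the strict rule 1 passed as higher and 4 as lower, without fatty acid oxidation and glycolysis (adjusted p = 0.0552 each) and insulin signalling (adjusted p = 0.148). Without high-fat diet 2 no list passed, without high-fat diet 3 there were 11, and without high-fat diet 1 there were 6.

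With carnitine on the high-fat diet, 3 features rose and 1 fell against the high-fat diet alone. The leading rises were the 2 non-coding features opposite Cish, which encodes an inhibitor of cytokine signalling that STAT5 induces. Gm17041 (chromosome 9, 107177579 to 107179037, minus strand; 479 bp of exon shared with Cish) rose from 40.4 ± 17.7 to 358 ± 200.1 CPM (SD, n = 3 each), a log2 fold change of 3.13 (SE 0.41, adjusted p = 0.00588 by edgeR). Gm17040 (chromosome 9, 107169634 to 107174391; 261 bp shared) rose from 8.75 ± 3.99 to 74.1 ± 54.1 CPM, a log2 fold change of 3.04 (SE 0.49, adjusted p = 0.00898). The row of Cish itself was too low to test, with 6, 24 and 10 counts in the carnitine libraries against 0, 8 and 4 on the high-fat diet and 0, 0 and 9 in control. Sphk2, a sphingosine kinase gene opposite the clock output gene Dbp and the ribosomal protein gene Rpl18, rose from 43.1 ± 1.83 to 151 ± 81.7 CPM (log2 fold change 1.80, SE 0.30, adjusted p = 0.00846). Flnc, the actin cross-linker of the Z-disc, has no opposite gene and fell from 385 ± 97.0 to 157 ± 20.9 CPM (log2 fold change −1.29, SE 0.24, adjusted p = 0.0256). Features with no opposite gene had a median of −0.32 here, and with each class scaled by itself Flnc was at −0.94 (SE 0.22, adjusted p = 0.144) and did not pass. Both features opposite Cish were higher in all 3 carnitine libraries than in any library of the other groups. Gm17041 passed in 6 of 6 fits that left out a library, Gm17040 and Sphk2 in 4 and Flnc in 2 (adjusted p up to 0.0325, 0.199, 0.384 and 0.431). None of the 4 passed in a fit of the 6 libraries alone, which called 0 genes (889 at an unadjusted p below 0.05), or with the residual rate as a covariate (log2 fold change 2.46 for Gm17041 and 2.23 for Gm17040, adjusted p = 0.112 each; 1.575 for Sphk2 and −1.23 for Flnc, adjusted p = 0.0612 each), and Gm17041 was at an adjusted p of 0.0873 with limma-voom. The count was 84 without carnitine 1, 1 without carnitine 2 or high-fat diet 1, 9 without high-fat diet 3, 57 with DESeq2, 26 without a filter, and 10 with a filter on CPM or without TMM.

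**Figure D3:**
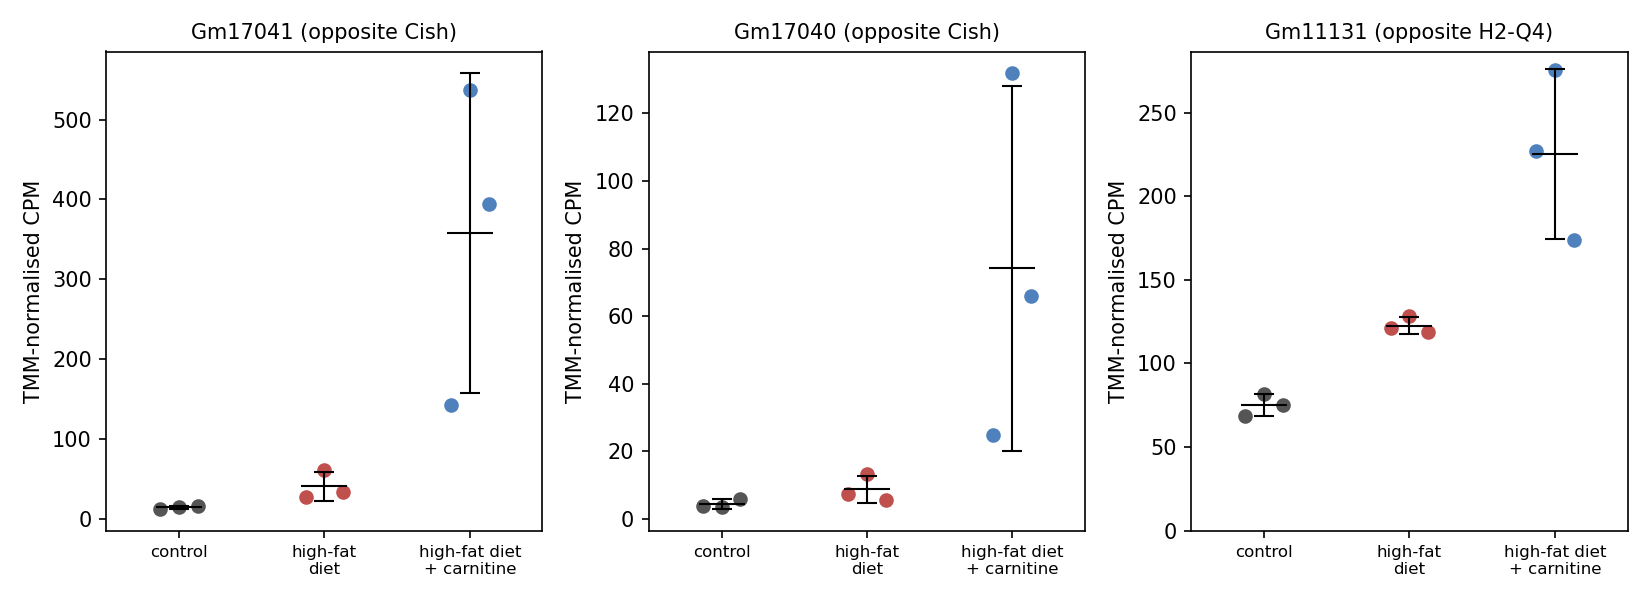
TMM-normalised CPM of Gm17041 and Gm17040 (both opposite Cish) and Gm11131 (opposite H2-Q4) in each library, with group means as long bars and 1 SD as whiskers (n = 3 per group). The carnitine mean of Gm17041 was 358 CPM against 40.4 on the high-fat diet and 14.0 in control.

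Among the gene lists, 17 passed as lower with carnitine and 1 as higher (camera). With an estimated correlation none of the 18 passed (smallest adjusted p = 0.405 with an estimated correlation, for antioxidant genes), and fry called 1, antioxidant genes (adjusted p = 0.0437). In none of them did a member pass over all genes. Muscle contraction was represented by fast fibre proteins, with 19 of 19 members lower (median log2 fold change −0.55, adjusted p = 3.97e-06), and by calcium handling and excitation-contraction coupling, with 19 of 22 lower (median −0.56, adjusted p = 3.82e-06). The 3 features with the most counts lie opposite fast fibre genes and were higher with carnitine, without passing. A930016O22Rik, opposite Ckm, was at 144400 ± 20110 against 112400 ± 6972 CPM, and Ube2c, opposite Tnnc2, at 107300 ± 10230 against 79070 ± 4562 CPM. Rabep2, opposite Atp2a1, was at 177800 ± 53980 against 148700 ± 5811 CPM, with carnitine 1 at 119000 CPM. The fast fibre gene Tpm1 was at 2884 ± 335 against 4731 ± 982 CPM (log2 fold change −0.71, SE 0.25), Mylpf at −0.62 (SE 0.22), and the kinase gene Camk2b at −1.36 (SE 0.35). Mitochondrial lists comprised respiratory complexes II to V (34 of 40 lower, median −0.42, adjusted p = 2.24e-06), respiratory complex I (28 of 38 lower, median −0.33, adjusted p = 0.00126) and pyruvate dehydrogenase with the tricarboxylic acid cycle (26 of 29 lower, median −0.38, adjusted p = 9.44e-05), with Uqcr10 at −0.99 (SE 0.31), Ndufa7 at −1.17 (SE 0.35) and Ogdh at −0.999 (SE 0.28). Carbohydrate and lipid lists comprised glycogen metabolism (14 of 15 lower, adjusted p = 0.000149), glucose uptake and glycolysis (16 of 20, adjusted p = 0.00126), insulin signalling (13 of 18, adjusted p = 0.0243), PPAR target genes (16 of 21, adjusted p = 0.00628) and lipid droplets (12 of 16, adjusted p = 0.0316). Among their members, Eno3 was at −0.59 (SE 0.24), Eif4ebp1 at −1.59 (SE 0.36, adjusted p = 0.0856), Pdk4 at −0.86 (SE 0.27) and Lpin1 at −1.01 (SE 0.30). Protein turnover and stress lists comprised cytosolic ribosomal proteins (66 of 76 lower, adjusted p = 2.24e-06), the proteasome with the ubiquitin ligases of atrophy (21 of 21, adjusted p = 3.42e-06), antioxidant genes (19 of 23, adjusted p = 0.00340), autophagy (17 of 23, adjusted p = 0.0174), heat shock proteins (14 of 19, adjusted p = 0.0174), glucocorticoid response (12 of 15, adjusted p = 0.0364) and muscle regeneration (8 of 9, adjusted p = 0.0420). Their members included Rps15 at −0.85 (SE 0.26), Fbxo40 at −1.29 (SE 0.35), Nfe2l2 at −1.44 (SE 0.58), Ctsd at −0.83 (SE 0.34), Bag3 at −1.19 (SE 0.31), Klf15 at −0.84 (SE 0.41) and Myf6 at −0.86 (SE 0.47). Adjusted over the list alone, 6 members of the proteasome and ubiquitin list, 4 of the heat shock list and 0 of the fast fibre list fell.

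The list that passed as higher was cell cycle, with 8 of 8 members higher (median 0.56, adjusted p = 0.00310, and 0 adjusted over the list alone). Of these members 7 share exon sequence with an opposite-strand gene. They include Ube2c, opposite Tnnc2 (log2 fold change 0.44, SE 0.21), Kif20a, opposite Cdc23 (0.65, SE 0.28), and Ccna2, opposite the exosome gene Exosc9 (0.61, SE 0.30). Across all tested features, those sharing exon sequence with an opposite gene had a median log2 fold change of 0.18 in this comparison and those with no opposite gene −0.32, beside the lower residual rates of carnitine 2 and 3 (5.32% and 5.03%). With the measured genes, each class scaled by itself, 1 list passed as lower, the proteasome and ubiquitin ligases (adjusted p = 0.0186, and 0.0142 by the strict rule; 0.793 and 0.799 with an estimated correlation), while fast fibre proteins had 10 of 16 lower (adjusted p = 0.882). Without carnitine 2 the count of lists was 9, and without carnitine 3 it was 12.

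Between carnitine on the high-fat diet and control, 32 features differed, 16 higher and 16 lower. The features opposite Cish led, with Gm17041 at a log2 fold change of 4.67 (SE 0.45, adjusted p = 9.16e-05 by edgeR) and Gm17040 at 4.06 (SE 0.53, adjusted p = 0.000723). Named genes that rose were Sec24a, at 113 ± 72.9 against 26.6 ± 5.18 CPM (log2 fold change 2.09, SE 0.36, adjusted p = 0.00768), Arhgef25 (1.73, SE 0.39), Oacyl (1.68, SE 0.32), Rb1, opposite Lpar6 and Rcbtb2 (1.63, SE 0.36), Zcchc17, opposite the fatty acid binding protein gene Fabp3 (1.41, SE 0.31), and Thra, opposite the clock repressor gene Nr1d1 (1.08, SE 0.23). Zcchc17 was at 727 ± 231 against 274 ± 124 CPM, while the row of Fabp3 was at 0.23 (SE 0.34, adjusted p = 0.877). Named genes that fell were Slc25a25, at 1.19 ± 1.27 against 27.0 ± 12.4 CPM (log2 fold change −4.39, SE 0.70, adjusted p = 0.00219), the transcriptional repressor Nfil3 (−2.58, SE 0.58), Ccny (−2.34, SE 0.51), the mTORC1 inhibitor Ddit4, at 9.45 ± 6.93 against 46.9 ± 10.97 CPM (−2.28, SE 0.47, adjusted p = 0.0300), the stress gene Gadd45g (−1.99, SE 0.43) and the collagen gene Col7a1 (−1.99, SE 0.46). Features that passed in all 6 fits leaving out a library were Gm17041, Gm17040, Gm11131, Gm41442 and Slc25a25, whereas the other calls passed in 0 to 3. Of the calls named here, Slc25a25, Gm17040, Nfil3, Ccny and Col7a1 did not pass with limma-voom (adjusted p = 0.166, 0.128, 0.312, 0.155 and 0.0814). Zcchc17 and Col7a1 did not pass with the residual rate as a covariate (adjusted p = 0.121 and 0.0885 by edgeR). Features with no opposite gene had a median of −0.20 here. With each class scaled by itself, Nfil3, Ccny and Col7a1 were not among the 10 calls. The count was 86 without carnitine 1, 5 without carnitine 2, 13 without carnitine 3, 12 without control 1 and 7 without control 3, and it was 66 with DESeq2, 60 without a filter, 18 without TMM and 10 in a fit of the 6 libraries alone.

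Lists that passed as lower against control numbered 10 and none passed as higher. With an estimated correlation none passed (smallest adjusted p = 0.613 with an estimated correlation). With the measured genes 5 of the 10 passed, fast fibre proteins (adjusted p = 1.76e-06), cytosolic ribosomal proteins (2.78e-05), calcium handling (0.000311, and 0.00759 by fry), glucocorticoid response (0.00522) and glycolysis (0.0395, and 0.108 by the strict rule), none of them with an estimated correlation (smallest adjusted p = 0.136 with an estimated correlation). The other 5 did not, the proteasome and ubiquitin ligases (adjusted p = 0.212), glycogen metabolism (0.312), muscle regeneration (0.312), pyruvate dehydrogenase and the tricarboxylic acid cycle (0.524) and respiratory complexes II to V (0.646). As named in the file, fast fibre proteins had 19 of 19 members lower (median log2 fold change −0.65, adjusted p = 9.74e-10), of which 9 fell when adjusted over the list alone and 0 over all genes. With the measured genes 16 of 16 were lower. On the common scale, abundant features opposite fast genes lay near control. Ube2c, opposite Tnnc2, was at 107300 ± 10230 against 105300 ± 17220 CPM, and A930016O22Rik, opposite Ckm, at 144400 ± 20110 against 146300 ± 20720 CPM. Rabep2, opposite Atp2a1, was at 177800 ± 53980 against 181000 ± 16090 CPM. Myh4, the IIB myosin gene, was at 18311 ± 3537 against 33621 ± 9624 CPM (−0.88, SE 0.25, adjusted p = 0.157), Myl1 at −0.81 (SE 0.24) and Mylpf at −0.81 (SE 0.22). Calcium handling had 20 of 22 lower (adjusted p = 3.49e-07), with Jph2 at −0.96 (SE 0.27), Camk2a at −1.22 (SE 0.38) and Casq1, opposite Gm17224, at −0.79 (SE 0.24). Glucocorticoid response had 12 of 15 lower (median −0.71, adjusted p = 0.000430). Of its members Ddit4 and Tsc22d3 (−1.95, SE 0.43, adjusted p = 0.0410) fell over all genes, and 3 fell adjusted over the list alone, while Sgk1 was at −1.85 (SE 0.65) and Klf15 at −1.08 (SE 0.41). The others were cytosolic ribosomal proteins (69 of 76 lower, adjusted p = 9.14e-09), glucose uptake and glycolysis (17 of 20, adjusted p = 8.68e-05), the proteasome and ubiquitin ligases (14 of 21, adjusted p = 0.00520), respiratory complexes II to V (26 of 40, adjusted p = 0.00659), glycogen metabolism (11 of 15, adjusted p = 0.00975), pyruvate dehydrogenase and the tricarboxylic acid cycle (21 of 29, adjusted p = 0.00975) and muscle regeneration (8 of 9, adjusted p = 0.0171). Among their members were Rps15 at −1.07 (SE 0.26), Pgk1 at −1.07 (SE 0.33) and Ppp1r3c at −1.97 (SE 0.49, adjusted p = 0.0977). The residual rate was 8.57%, 6.92% and 8.72% in the control libraries, against 9.88%, 5.32% and 5.03% with carnitine. Without carnitine 2 the count of lists was 5 and without carnitine 1 it was 16.

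Several genes of carnitine transport and use had few counts. Of the panel of 18 genes, Slc22a5 (the carnitine transporter of the plasma membrane), Cpt1a, Cpt1b, Scd1, Ppargc1a and Adipoq were too low to test. Slc22a5 had at most 4 counts in any library and Cpt1b at most 7, so changes in them were not detectable in these counts. Both have no opposite gene, and features of that class held 12.1% of all counts, so low counts here need not mean low expression. None of the panel genes that were tested changed in any comparison. Cpt2 was at 8.96 ± 4.02 CPM on the high-fat diet, 6.93 ± 2.33 in control and 5.32 ± 4.31 with carnitine. Crat, the carnitine acetyltransferase gene, shares exon sequence with Dolpp1 and Gm16323 and was at 87.3 ± 9.14, 69.0 ± 25.7 and 48.9 ± 9.12 CPM in the same order. The atrophy ligase genes were higher on the high-fat diet than in control without passing, Trim63 at 403 ± 202 against 190.4 ± 24.6 CPM (log2 fold change 1.08, SE 0.30, adjusted p = 0.195 by edgeR) and Fbxo32, opposite Gm15943, at 291 ± 92.6 against 140.4 ± 35.2 CPM (1.05, SE 0.34, adjusted p = 0.400). Gm15943, which also lies opposite Klhl38, held far more counts than the row of Fbxo32. It had 13387, 11852 and 17333 counts on the high-fat diet, 6343, 4517 and 7699 in control and 4940, 9876 and 10245 with carnitine, and did not pass.

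Fold changes of the diet and of carnitine on the diet were set against each other to ask whether carnitine moved expression back toward control. Of the 4 features changed by the diet, 3 had a carnitine mean closer to control. This tally cannot show a reversal, since the features were chosen by the same high-fat diet libraries. Its value under no effect was not computed. Zfp142 was at 133 ± 67.6 CPM with carnitine, against 49.3 on the high-fat diet and 153 in control (carnitine against high-fat diet, log2 fold change 1.43, SE 0.30, adjusted p = 0.0655). Gm26714 was at 0.91 (SE 0.29, adjusted p = 0.226) and Tecpr2 at 0.25 (SE 0.25, adjusted p = 0.738), while Slc25a25 was further from control at 1.19 ± 1.27 CPM (adjusted p = 0.711). Across the 7523 features, which are not independent replicates, Pearson's r was −0.409, Spearman's rho −0.420 and the covariance −0.176. Both fold changes share the high-fat diet libraries. In 50 simulations with no effect in any group, r averaged −0.481 (−0.506 to −0.453) and the covariance −0.164 (−0.177 to −0.151). The observed covariance thus lay within the range that shared libraries alone gave, and the observed r was less negative than any simulated value. Drawn assignments of the 9 real libraries gave r down to −0.778, outside the simulated range.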

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

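Counts of changed genes depended on the processing, and the cause was not tested. Some of the fits also held fewer features or libraries. The comparisons are given in the order high-fat diet against control, carnitine against high-fat diet and carnitine against control, with 4, 4 and 32 genes. RLE normalisation, leaving out the 20 most abundant features and a 2-fold threshold kept these counts within 1.5 times. Library totals without TMM gave 0, 10 and 18, and moved the median log2 fold change of all features to 0.173, −0.203 and −0.027. No filter gave 68, 26 and 60, a CPM filter 40, 10 and 42, DESeq2 46, 57 and 66, limma-voom 18, 4 and 30, and fits of the 6 libraries compared 40, 0 and 10. At an unadjusted p below 0.05, the counts of 0 stood beside 528 features without TMM and 889 in the fit of 6 libraries. Leaving out a library gave 0 to 13, 1 to 84 and 5 to 86.

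Alternatives chosen after seeing the data were the residual rate as a covariate (35, 1 and 53 genes), opposite-exon features alone (0, 6 and 13), features with no opposite gene alone (2, 0 and 7) and the measured genes by the 5-fold rule (2, 1 and 10) and the strict rule (2, 1 and 9). The last 4 tested fewer features.

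Gene lists numbered 3, 18 and 10. With an estimated correlation there were 0, 0 and 0, with fry 0, 1 and 0, with the measured genes 8, 1 and 5 by the 5-fold rule and 5, 1 and 4 by the strict rule. RLE normalisation gave 3, 18 and 10. Leaving out a library gave 0 to 11, 9 to 24 and 5 to 16.

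The replicate number as a block gave 10, 3 and 31 genes and 3, 18 and 10 lists. Deviations of log2 CPM from the group means were correlated between libraries of different groups. Libraries of the same number gave −0.164 to 0.142 over 9 pairs, against −0.154 to 0.187 for those of different numbers, so the numbers were not taken as pairs. With the block, the log2 fold changes of Plin2 (−0.04679) and Slc2a4 (0.0027688) in high-fat diet against control reversed.

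The correlation for the reversal, −0.409, ranged from −0.565 to −0.265 when a library was left out. Of 1700 values of named genes under the alternatives, 1544 kept direction and side of the threshold, 77 no longer passed, 60 newly passed and 19 reversed, none of them of a called gene. Leaving out a library gave these ranges of log2 fold change for the genes that reversed. In high-fat diet against control they were −0.00047877 to 0.71197 for Cpt2, −0.27555 to 0.45622 for Plin2, −0.31094 to 0.12872 for Slc2a4 and −0.011528 to 0.16594 for Ucp3. In carnitine against high-fat diet they were −0.85824 to 0.0033442 for Fbxo32 and −0.23666 to 0.88221 for Plin2. In carnitine against control they were −0.61512 to 0.89891 for Angptl4, −1.19 to 0.10312 for Cpt2, −0.61664 to 0.0063109 for Pdk4, −0.16153 to 0.96149 for Plin2, −0.4897 to 0.039013 for Slc25a20 and −0.045855 to 0.4659 for Trim63. Several of these genes had few counts, which limits them.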

Other observations

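Tests chosen only after the result was seen were those of RNA made from the opposite strand, of the residual rate for the gene lists, of a single library and of STAT5 signalling, and the comparison of list members under both scalings. Every feature named in this part was also chosen after its values were seen.

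Among the features that rose with carnitine against control were 4 opposite immune genes, which were not tested as a group. Gm11131, opposite the class I gene H2-Q4, rose from 75.1 ± 6.55 to 225 ± 50.9 CPM (SD, n = 3 each), a log2 fold change of 1.59 (SE 0.24, adjusted p = 0.00135 by edgeR), with 123 ± 5.11 CPM on the high-fat diet alone. Gm36043, opposite Cd274, the gene of the checkpoint ligand PD-L1, rose by 2.06 (SE 0.45, adjusted p = 0.0342), A930015D03Rik, opposite H2-T22, by 2.29 (SE 0.53, adjusted p = 0.0456), and Gm20496, opposite Psmb8 and Tap2, by 1.31 (SE 0.30, adjusted p = 0.0462). Of these, Gm11131 passed in 6 of 6 fits that left out a library, Gm36043 in 2, and A930015D03Rik and Gm20496 in 1. None of the 4 passed in carnitine against high-fat diet (adjusted p = 0.199 for Gm11131). Class I genes in their own rows did not pass against control, with H2-K1 at 0.38 (SE 0.40), H2-D1 at 0.21 (SE 0.37), H2-Q4 at 0.70 (SE 0.62) and B2m at 0.27 (SE 0.66). The list of antigen presentation had 7 of 9 members higher (adjusted p = 0.330, and 0.819 with an estimated correlation).

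Of the features opposite fibre type and fuel genes, Myhas, Gm49540, Gm15441 and Mhrt did not pass in any comparison, whereas Gm26588, opposite the lipase gene Mgll, rose with carnitine against control (log2 fold change 1.60, SE 0.32, adjusted p = 0.0198 by edgeR). Myhas, opposite the IIX myosin gene Myh1, was at 14310 ± 4220 CPM in control, 20730 ± 6436 on the high-fat diet and 25530 ± 11090 with carnitine (SD, n = 3 each). Gm49540, opposite the myoglobin gene Mb, was at 17100 ± 6345, 23390 ± 5480 and 30420 ± 12370 CPM, and Gm15441, opposite Txnip, at 2592 ± 230, 3955 ± 693 and 3979 ± 627 CPM. Dvl2, opposite Acadvl, had means of 3270, 3963 and 5225 CPM in the same order. The carnitine libraries were uneven for Myhas (36850, 14690 and 25060 CPM in carnitine 1, 2 and 3) and Gm49540 (42990, 18260 and 30000 CPM). For both, carnitine 2 lay within the range of the control libraries (11110 to 19090 and 13370 to 24430 CPM). Other abundant features were lowest on the high-fat diet. Rabep2 had means of 181000, 148700 and 177800 CPM, A930016O22Rik of 146300, 112400 and 144400, and Ube2c of 105300, 79070 and 107300. Neither Dvl2 nor these passed in any comparison. Mhrt, opposite the slow myosin gene Myh7, had 815 counts in control 2 and 458 in carnitine 2, against 0 to 115 in the other libraries. Of 15 cell type lists, 4 had 5 or more tested members (endothelial, smooth muscle, fibro-adipogenic and neuromuscular junction) and did not pass, and the other 11 could not be tested. The adjusted p for endothelial genes was 0.137, 0.374 and 0.752 in the order high-fat diet against control, carnitine against high-fat diet and carnitine against control.

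Most counts lay on features opposite abundant muscle genes. Of 758 non-coding features with a protein-coding gene opposite, 81.27% held more counts than that gene, which argues against RNA made from the opposite strand and counted correctly as the cause throughout. This share was chosen after the pattern was seen and partly restates it. Counting against the strand of the library is a candidate explanation. Under it, the row of a gene with no opposite gene would hold only a residue of that gene's reads. Over 426 pairs, which are not independent replicates, fold changes of feature and gene correlated with a Spearman rho of 0.2773, above the highest of 1000 shuffled pairings (0.1468). Transcription shared by both strands at a locus would also raise this correlation, and the reads themselves were not at hand.

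Many gene lists passed as lower with carnitine on the high-fat diet. With every library thinned to 2315985 counts 16 of the 17 still passed as lower, which argues against a difference in depth. With each class of features scaled by itself 1 of 17 still did, by the 5-fold and by the strict rule, so the residual rate of each library may account for most of these calls. That scaling also removes any broad fall shared by a class, whatever its cause, so it does not single out the residual rate. These lists also held fewer members. Lower expression of these pathways would lower members measured through a non-coding opposite feature too, but the median log2 fold change of these 27 members, which are not independent, was 0.0966 (SE 0.0733) with each class scaled by itself and 0.333 (SE 0.0732) with 1 TMM for all features, against −0.103 (SE 0.0423) and −0.476 (SE 0.0417) for members with no opposite gene. Lower expression stays open for the proteasome and ubiquitin list, which still passed, and for members not measured through such a feature.

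The features opposite Cish rose with carnitine. Leaving out any of the 6 libraries gave a log2 fold change of Gm17041 of at least 2.707, which argues against a single library. With the residual rate of each library as a covariate it was 2.458 (SE 0.464), against 3.13 (SE 0.41) before, and the call ended (adjusted p = 0.112, against 2.24e-12 with DESeq2, 0.0873 with limma-voom and up to 0.0325 when a library was left out), with a smaller fold, a larger SE and 1 residual degree of freedom fewer. Growth hormone or cytokine signalling through STAT5, which induces Cish and Socs2, could raise them, but of Socs2 and Socs3 0 were tested and 0 passed, with at most 11 and 4 counts in a library, so this cannot be told apart from other causes with so few counts. The row of Cish itself, at 6, 24 and 10 counts with carnitine against 0, 8 and 4, was too low to test.

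The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. For genes, 1 split (the real one) gave a count as large in high-fat diet against control (4, highest other 1), 1 in carnitine against high-fat diet (4, highest other 1) and 1 in carnitine against control (32, highest other 0). For gene lists, 10 splits gave as many in high-fat diet against control (3, highest other 12), 3 in carnitine against high-fat diet (18, highest other 23) and 4 in carnitine against control (10, highest other 19). List counts several times the real one in other splits of the diet comparison show that such counts also arise in groupings other than the diet. Their cause was not tested. For the reversal, 85 of 100 drawn assignments of the 9 libraries gave a correlation as negative as −0.409 (most negative other −0.778), so chance is not excluded.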
